A study of Mus musculus with 4 samples.

How the data were processed

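Perfused brains of female CBA/CaH and C57BL/6 mice, naive or with experimental cerebral malaria (ECM), were profiled on Affymetrix Mouse Genome 430 2.0 arrays. Per the labels' protocols, mice were perfused through the heart with 20 mL of buffered saline, brain RNA was extracted with TRIzol and passed over silica columns with DNase treatment, and equal amounts of RNA from 6 mice were pooled for 1 array per group. Groups were taken from the sample titles. The infecting dose was not used here because the labels write it in forms that cannot be told apart, and the day of tissue collection in C57BL/6 mice is not given in the sources used here.

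The deposited values are probe set intensities on a linear scale. The submitters' processing notes name MAS5, which gives 1 background-corrected intensity per probe set, and the labels name GeneSpring 7 and, for 3 of the arrays, GeneChip Operating Software 1.1.1. Per the labels, the authors divided each measurement by the array's 50th percentile and kept genes flagged as present with a level of at least 50 before calling changes of 2.5-fold. The deposited intensities themselves were not divided in this way, since their medians over listed, non-control probe sets were 127.5 and 121 in the naive and ECM pools of CBA/CaH and 127 and 117 in those of C57BL/6. They ran from 3.77 to 11265. Between 41.4% and 42.8% of the cells of each array were blank, for a reason not given in the sources used here. Of 45037 non-control probe sets 22201 had a value on all 4 arrays and 14707 on none. For the 2407 probe sets blank on 1 array, the median of the values on the other arrays was 30.6, and 76.3% lay under 50.

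Each array was scaled so that its median over listed, non-control probe sets equalled the mean of the 4 medians, 123 (factors of 0.967, 1.02, 0.970 and 1.05 for CBA/CaH naive and ECM and C57BL/6 naive and ECM). Values under 50 were then set to 50. Blank cells were also set to 50. The plan made before the data were examined did not foresee blanks, so this choice and its alternatives were made afterwards. Setting values to a floor makes a fold against a listed dim value a lower bound and hides changes among dim genes. A fold against a blank cell is not a bound, because the level behind a blank is not known. The 64 control probe sets were left out of scaling and gene tables.

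Probe sets were named through a table of the platform's annotation, with symbols updated through Entrez identifiers to the RefSeq annotation of GRCm38.p6, which was used for names only. Of the non-control probe sets 34945 had 1 gene symbol, of which 34741 matched by identifier, 932 had several and were not named, and 9160 were unnamed here. Each of 18193 genes was represented by the probe set with the highest mean over the 4 arrays. A gene was measured in a comparison when at least 1 of the 2 arrays reached 50, and called when the floored intensities differed at least 2.5-fold. A gene under the floor or blank on 1 of the 2 arrays was measured through the other only, so its fold could go only 1 way. ECM was compared with naive within each strain, and CBA/CaH with C57BL/6 within each state. With 1 pooled array per group the number of arrays limits the precision, no difference has a replicate check and no p-value was computed. The only repeat measurements were probe sets of 1 gene, whose log2 folds gave a pooled SD when both values were at least 50.

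A total of 29 gene lists were fixed before the data were examined, covering interferon-stimulated genes, chemokines, cytokines, antigen presentation, markers of blood and brain cell types, endothelium, complement, stress responses and reference genes. Each list's median log2 fold was placed among 10000 random lists of measured genes of the same size, matched on mean level in 20 bins. A list was said to stand apart above the percentile of 97.5 or below 2.5. In all 57 list medians were computed over both strains. Such percentiles describe these arrays and are not tests of the conditions. No percentile was given for lists with fewer than 3 measured genes.

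The genes named were chosen by a rule fixed beforehand. In each comparison of ECM with naive it took the 10 called genes with the highest fold and the 8 with the lowest among those at or above the floor on both arrays, the 6 called genes with the highest ECM value among those under the floor or blank in the naive pool, and up to 4 called members of each list. Between strains it took the 6 genes per direction with the largest ratio of folds above the floor on all 4 arrays and the 5 per direction with the largest naive difference. Predicted and clone names were passed over within the strains, 21 calls in all. Genes of the lists outside this rule, and those of the closing section, were chosen after their values were seen.

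Every result was recomputed with the deposited values unscaled, scaled to a common 2% trimmed mean or quantile normalized, with floors of 25 and 100, with no floor for genes listed on both arrays, with a threshold of 2-fold, with the median of all probe sets of a gene, without probe sets of the _x_at and _s_at kinds, and with random lists not matched on level. After the data were seen 3 alternatives were added: genes with a value on both arrays only, blank cells set to 113 (the 95th percentile of the other arrays' values where 1 array was blank), and the median taken over probe sets listed on all 4 arrays.

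The steps were tested on simulated data in which 200 genes were changed by known folds, with noise equal to the spread between probe sets and an ECM array 1.3 times as bright as the naive one. The changed genes had a naive level of at least 200, so the recovery given here says nothing of dim genes. Of 50 genes changed 5-fold all were recovered in the CBA/CaH simulation and in that of C57BL/6, of 50 changed 3-fold 37 and 41, and of 50 changed 2-fold, which lie under the threshold, 14 and 11. Of unchanged genes 4 of 10345 and 7 of 10392 were called. The simulated ECM array was made from the naive one, so a cell blank on 1 was blank on both. No call against a blank cell could therefore arise. The noise held no differences between mice, pools or hybridisations, so these counts are not a rate of false calls in the data. Of 200 random lists of unchanged genes 5.5% and 6% stood apart. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.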

Results

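Gene expression was measured in perfused brains of female mice of the inbred strains CBA/CaH and C57BL/6, 6 to 7 weeks old, that were either naive or had experimental cerebral malaria (ECM). ECM is the fatal neurological syndrome that follows infection of susceptible mice with the rodent parasite Plasmodium berghei ANKA, and both strains are known to be susceptible. RNA of 6 mice was pooled in equal amounts for each of the 4 combinations of strain and state, and each pool was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, so no group had a replicate. The labels place tissue collection in CBA/CaH mice on days 6 to 7 after infection. Of 45037 probe sets other than controls, 26376 carried an intensity in the naive CBA/CaH pool, 26346 in the CBA/CaH ECM pool, 25773 in the naive C57BL/6 pool and 25740 in the C57BL/6 ECM pool. The remaining cells were blank.

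All comparisons below set 1 array against 1 array, and no p-value was computed. A gene was called higher or lower when its scaled intensities, with values under 50 and blank cells set to 50, differed at least 2.5-fold, and the words rose and fell are used of such genes only. A fold against a listed value under this floor is a lower bound and is given as "at least". A fold against a blank cell is given as "over the floor" and is no bound, since for probe sets blank on 1 array only 76.3% of the values on the other arrays lay under 50. The repeat measurements in the design were the different probe sets of 1 gene on the same array, whose log2 folds had a pooled SD of 0.36 in CBA/CaH (4056 genes) and 0.38 in C57BL/6 (3943 genes). This spread covers error within an array and not differences between mice or pools.

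The first comparison asked how the brain of CBA/CaH mice with ECM differed from the naive brain. Of 10954 genes measured, 328 were higher and 31 lower in the ECM pool. The genes that rose most were targets of interferon. Iigp1, an interferon-inducible GTPase, reached 3555 from a naive value of 38.9 under the floor (at least 71.1-fold), and its relatives Igtp (56.6-fold, from 64.2 to 3634), Irgm1 (24.4-fold) and Gbp2 (at least 55.5-fold) rose with it. Ifit3 (27.8-fold), Rtp4 (26.6-fold), Ifi35 (18.2-fold) and Ifitm3, a membrane protein that restricts virus entry (17.7-fold, from 265 to 4697), were also among the 10 genes with the highest folds above the floor on both arrays, as were Lyz1 (20.1-fold), Tgm2 (16.1-fold), Ctla2a (14.9-fold) and Lgals9 (14.3-fold). Lyz1 was read from a probe set of the _x_at kind and had no fold when the _x_at and _s_at kinds were left out. No naive value was listed for Ifi27l2a, Gbp6, Psmb8 and Psmb9, which reached 2405, 1913, 1699 and 1672.

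Of the 28 measured interferon-stimulated genes, 25 rose and none fell, with a median log2 fold of 3.70. All 3 others, Stat2, Dhx58 and Socs1, were above their naive level by less than the threshold, with log2 folds of 1.28, 1.22 and 0.22. Among genes of MHC class I and antigen processing, which present peptides to cytotoxic T cells, 13 of 14 rose (median 2.52). The immunoproteasome subunits Psmb8 and Psmb9 were 34.0-fold and 33.4-fold over the floor, the peptide transporter subunit Tap2 was 13.2-fold over it and the heavy chain H2-K1 was higher by at least 11.7-fold. Of 9 MHC class II genes on the array 5 were measured, and all 5 rose (median 3.24), led by the invariant chain Cd74, which went from 46.8 to 1389, and by H2-Aa at 855 with no naive value listed. Cd74, H2-Aa, H2-Ab1 and H2-Eb1 were under the floor or blank in the naive pool. They were measured through their ECM value only and could not have been called lower. Each of these 3 medians lay at the 100th percentile of 10000 random gene lists matched on expression level.

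Chemokines and markers of blood leukocytes were higher as well. Of 13 measured chemokines 9 rose (median 1.67, 100th percentile, or 0.41 without genes that had a blank cell, where the list no longer stood apart), among them the interferon-inducible ligands of the receptor Cxcr3: Cxcl11 reached 1601, Cxcl10 1284 and Cxcl9 790.1, each with no naive value listed. Ccl12 reached 659.6 from a blank cell. Of 27 cytokines and cytokine receptors on the array 12 were measured (median 0.95, 100th percentile, or 97.2 with blank cells set to 113). Of these 4 rose, namely the oncostatin M receptor Osmr (at least 7.38-fold), Il18bp (5.22-fold over the floor), Tnfrsf1a (3.58-fold) and Csf1 (3.43-fold). Markers of T cells and NK cells rose in 3 of 7 cases, with the granzymes Gzmb and Gzma at 683 and 437.9 and Ms4a4b at 182, all from blank naive cells. Their median of 1.12 (100th percentile) rested on the value given to those cells, and was 0.09 (percentile 60.0) with blank cells set to 113. Among monocyte and macrophage markers 10 of 12 rose (median 1.96, 100th percentile), including Plac8 (20.4-fold over the floor), Lyz2 (9.91-fold), Fcgr1 (at least 6.23-fold) and Ms4a6d (5.36-fold over the floor). Of 11 neutrophil markers on the array 2 were measured, of which the calprotectin subunit S100a8 rose 3.24-fold and S100a9 was at least 2.40-fold above naive. None of the B cell markers was measured in this strain at the probe set that represented it.

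Markers of the glia resident in the brain rose in part. Of 14 measured microglia markers 8 rose (median 1.49, 100th percentile), with C1qc at 9.74-fold, C1qb at 7.54-fold, C1qa at 6.64-fold and the signalling adaptor Tyrobp at 6.14-fold, whereas the chemokine receptor Cx3cr1 (log2 fold -0.94) and the purinergic receptor P2ry12 (-0.63) were below their naive level without passing the threshold. The 3 C1q chains were also counted among the complement genes, of which 7 of 10 rose (median 1.69, 100th percentile), Serping1, the inhibitor of the first complement component, at 12.7-fold among them. Reactive astrocyte genes rose in 12 of 17 cases (median 1.81, 100th percentile): Cebpd by 13.9-fold, Serpina3n from 77.4 to 927, Lcn2 to 11.0-fold over the floor, Socs3 by at least 9.72-fold and the intermediate filament Gfap by 6.05-fold (from 382 to 2310). Homeostatic astrocyte genes stayed within the threshold in all 12 cases (median 0.28, percentile 92.1).

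Of 13 genes of endothelial activation and coagulation 3 rose (median 1.03, 100th percentile), the adhesion molecules Icam1 (6.38-fold over the floor) and Vcam1 (3.02-fold) and the sterol hydroxylase Ch25h (6.82-fold over the floor). In the list of brain endothelial junction and transport genes only Esam passed (2.87-fold) among 17, with a list median of 0.16 (percentile 68.2). Glucocorticoid-responsive genes were higher in 7 of 15 cases (median 1.20, 100th percentile), with the cell cycle inhibitor Cdkn1a at 5.48-fold, Sult1a1 at 4.56-fold, Pdk4 at 4.04-fold and Tsc22d3 at 3.80-fold. Immediate early genes, which neurons and other cells switch on within minutes of a stimulus, had a median of 0.94 (100th percentile), although only Fos (5.38-fold) and Junb (4.22-fold) of 16 passed the threshold. In the kynurenine, nitric oxide and arginine list 2 of 5 genes rose, Ido1 (3.84-fold) and Acod1 (2.89-fold over the floor), with a median of 0.99 (percentile 99.8). The inflammatory caspases Casp1 (3.33-fold over the floor) and Casp4 (2.76-fold over the floor) and the apoptotic Casp8 (at least 3.18-fold) were the 3 of 12 cell death genes that rose (median 0.93, 100th percentile), and the replication factor Mcm5 (3.36-fold) was the 1 of 9 cell cycle genes (median 0.77, percentile 99.95). Hypoxia response genes had a median of 0.25 (percentile 88.8), with the vasodilator peptide Adm (at least 5.20-fold) and Pfkfb3 (2.70-fold) higher among 16. In the list of heme, metal and oxidative stress genes 2 of 12 rose, the heme oxygenase Hmox1 (5.07-fold over the floor) and the metallothionein Mt2 (2.62-fold), with a list median of 0.01 (percentile 24.8).

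None of 19 neuronal genes (median -0.03, percentile 6.12), 14 myelin and oligodendrocyte genes (median -0.23, percentile 0.24) and 8 reference genes (median 0.05, percentile 35.9) passed the threshold, nor did 8 choroid plexus (median 0.19, percentile 73.0) or 3 platelet markers (median 0.11, percentile 58.0). The single measured red cell marker, Bpgm, had a log2 fold of -0.20. The 8 genes that fell most above the floor on both arrays were Mir124a-1hg, the host transcript of the neuronal microRNA miR-124 (3.43-fold lower, from 446 to 130), the imprinted antisense RNA Kcnq1ot1 (3.27-fold), the vascular phosphatase Ptprb (3.22-fold), Pde1a (3.21-fold), Eogt (2.98-fold), Evi5 (2.69-fold), Nwd2 (2.69-fold) and Pitpnc1 (2.67-fold). Beside these stood the pituitary hormone genes, with a median of -1.07 over 3 genes (percentile 0.06), which turned to 0.10 (percentile 60.2) with blank cells set to 113. Pomc, Prl and Gh were listed at 282, 105 and 89.0 in the naive pool and had no value in the ECM pool, and only Pomc passed, its naive value 5.65-fold over the floor.

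In 101 of the 328 genes called higher the naive cell was blank, and 158 were above the floor on both arrays. Of 108 other bright probe sets of these genes, 79 (73.1%) passed the threshold the same way, against 7 of 15 (46.7%) for the genes called lower. A dimmer probe set gave a much smaller log2 fold than the one reported for Psmb8 (0.32), Cxcl9 (0.23), Rtp4 (0.05), Osmr (0.04), Csf1 (0.05) and Tsc22d3 (0.04), and the calls of Osmr, Csf1, Tsc22d3, Vcam1, Pfkfb3, Mcm5, Fcgr1, Ms4a4b, Ptprb, Kcnq1ot1, Pde1a, Eogt, Evi5 and Pitpnc1 ended when the median of all probe sets was taken. With blank cells set to 113 the calls of Acod1, Casp1, Casp4, H2-Eb1, Hmox1, Il18bp, Ms4a4b, Ms4a6d and Pomc ended, and with the floor at 100 those of Acod1, Casp1, Casp4, Casp8, Eogt, Ido1, Kcnq1ot1, Mcm5, Ms4a4b, Ptprb and S100a8.

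**Figure D1:**
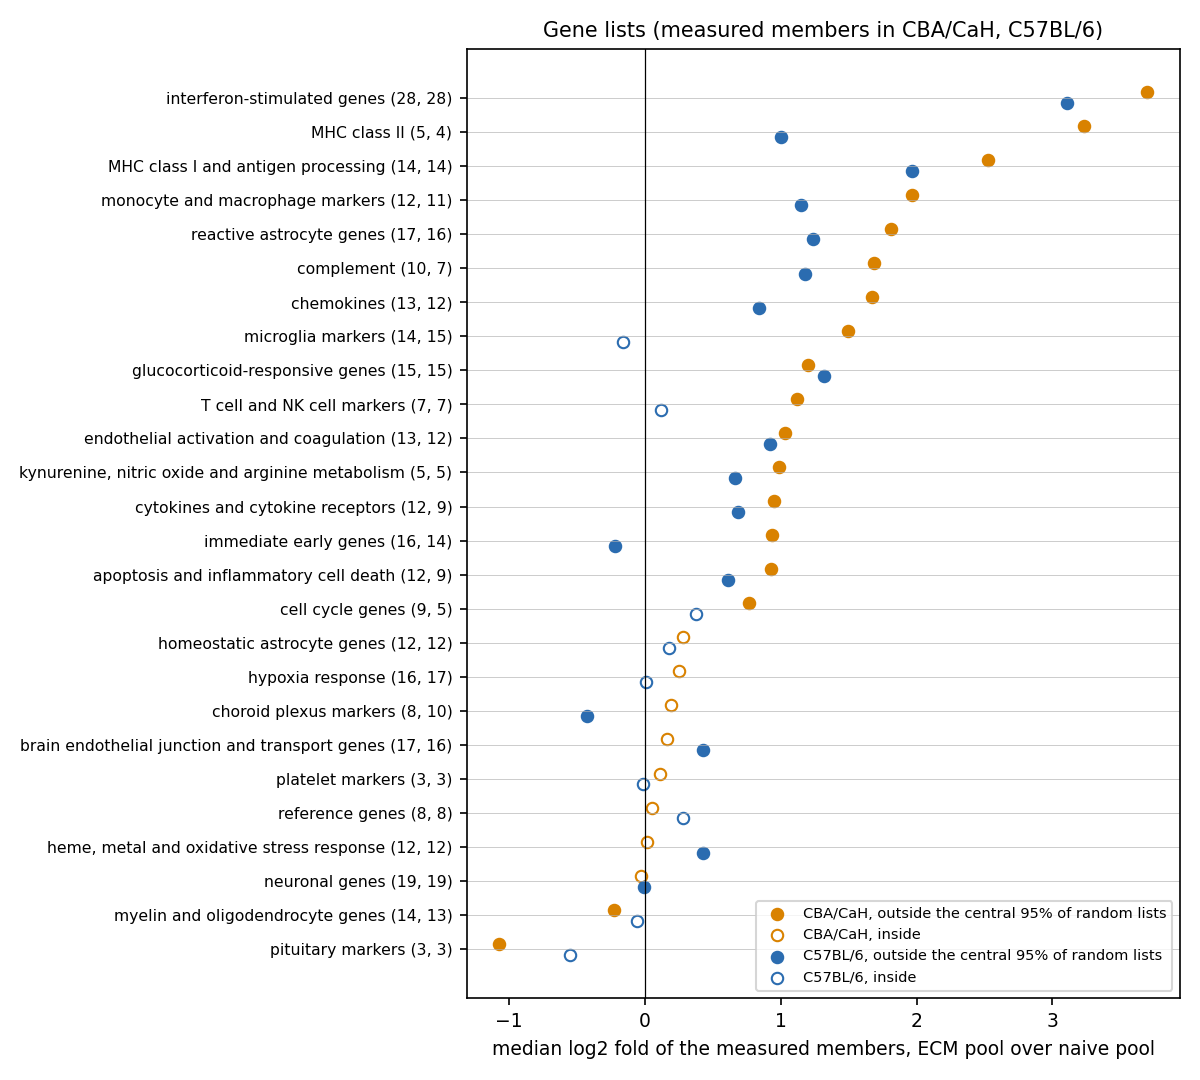
Median log2 fold, ECM pool over naive pool, of the measured members of each gene list in CBA/CaH (orange) and C57BL/6 (blue), with the number of measured members in brackets and filled points for medians outside the central 95% of 10000 random lists matched on level. Interferon-stimulated genes had the highest median in both strains (3.70 and 3.11), and microglia markers and immediate early genes lay above 0 in CBA/CaH and below 0 in C57BL/6, where the microglia median was 0.23 with the floor at 100.

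The same comparison in C57BL/6 mice gave 247 genes higher and 93 lower in ECM among 10885 measured. Interferon targets led again. The highest folds above the floor on both arrays were those of Ifit3 (22.2-fold, from 114 to 2531), the protease inhibitor homologue Ctla2a (22.2-fold), Rtp4 (16.4-fold), Igtp (15.5-fold), Xaf1 (12.1-fold), Irgm1 (10.7-fold), Gbp7 (10.5-fold), Ifit2 (10.5-fold), Ifitm3 (9.25-fold) and Cebpd (8.73-fold). Of genes listed under the floor in the naive pool, Gbp2 reached 1997, Iigp1 1916, Ifit1 1268, Rsad2 1149 and the iron-binding protein Lcn2 1018, and Ifi27l2a reached 1063 from a blank cell.

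Of 28 interferon-stimulated genes 24 rose (median 3.11), and of 14 genes of MHC class I and antigen processing 10 rose (median 1.97), with Psmb8 at least 17.2-fold and H2-K1 8.45-fold above naive and Psmb9 8.16-fold and Tap1 7.95-fold over the floor. Both medians lay at the 100th percentile, under the same limit as in CBA/CaH. The log2 folds of the 4 measured H2-K1 probe sets ran from 0.22 to 3.08 (3 from 1.27 to 3.55 in CBA/CaH), and the highest, from a probe set of the _x_at kind, is the one given. In MHC class II, H2-Aa (3.87-fold) and Cd74 (2.54-fold) rose among 4 measured genes (median 1.0, percentile 99.8, or 90.5 without _x_at and _s_at probe sets). Chemokines rose in 5 of 12 cases, with Cxcl10 at 935, Ccl12 at 198, Cxcl9 at 190.5 and Cxcl11 at 185 from blank cells. Their median of 0.84 (100th percentile) turned to -0.34 (percentile 12.4) without genes that had a blank cell. Osmr (3.47-fold) was the 1 of 9 measured cytokine and receptor genes, of 27 on the array, that rose (median 0.68, percentile 99.9, or 83.9 with blank cells set to 113). Of 20 T cell and NK cell markers on the array 7 were measured, and their median of 0.12 lay inside the random lists (percentile 62.2). Gzmb (6.93-fold over the floor) and Gzma (4.06-fold over the floor) rose among them. Monocyte and macrophage markers rose in 5 of 11 cases (median 1.15, 100th percentile), with the chitinase-like protein Chil3 (at least 11.4-fold), Plac8 (9.67-fold over the floor), Fcgr4 (3.24-fold over the floor) and Cd68 (2.72-fold). Of 3 neutrophil markers measured among 11 on the array, S100a8 (5.64-fold) and S100a9 (4.94-fold) rose (median 2.30, 100th percentile). The 1 measured B cell marker, the immunoglobulin heavy chain Ighm, went from 270 to 146, within the threshold.

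Microglia markers did not rise as a list in C57BL/6. Of 15 measured, C1qb rose (2.52-fold), Fcrls (at least 3.55-fold) and Olfml3 (at least 3.12-fold) fell, and the median was -0.16 (percentile 6.42), or 0.23 with the floor at 100, where the calls of Fcrls and Olfml3 ended. Complement genes rose in 2 of 7 cases, Serping1 (3.66-fold) and C1qb, with a median of 1.18 (100th percentile). Among reactive astrocyte genes 7 of 16 rose (median 1.23, 100th percentile), led by Lcn2 (at least 20.4-fold), Cebpd, Serpina3n (at least 8.57-fold) and Socs3 (at least 5.01-fold), while none of the 12 homeostatic astrocyte genes passed (median 0.18, percentile 46.3). Of 12 genes of endothelial activation and coagulation 3 rose (median 0.92, 100th percentile), Icam1 (4.81-fold over the floor), Ch25h (4.66-fold over the floor) and the fenestral diaphragm protein Plvap (2.63-fold). Among 16 brain endothelial junction and transport genes Esam rose (2.66-fold) and Slco1c1, the thyroxine transporter of the blood-brain barrier, fell (3.33-fold, from 717 to 215), with a median of 0.43 (percentile 99.1). This list no longer stood apart with the floor at 25 (percentile 73.4) or with the median of all probe sets. Glucocorticoid-responsive genes rose in 7 of 15 cases (median 1.32, 100th percentile): Cdkn1a by 5.47-fold, Sult1a1 by 4.87-fold, Tsc22d3 by 3.70-fold and the kinase Sgk1 by 3.52-fold.

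Of 14 immediate early genes measured in this strain, Arc (5.98-fold) and Nr4a1 (2.99-fold) fell and none rose. Their median was -0.22 (percentile 1.76), and the list no longer stood apart with the floor at 25, with the median of all probe sets or among lists not matched on level (percentile up to 3.66). In the list of heme, metal and oxidative stress genes Hmox1 rose (3.78-fold over the floor) among 12 (median 0.43, percentile 98.1, or 97.3 with no floor). No gene passed among 17 hypoxia response genes (median 0.01, percentile 17.6), 5 genes of kynurenine, nitric oxide and arginine metabolism (0.66, percentile 98.1), 9 cell death genes (0.61, percentile 99.6), 5 cell cycle genes (0.37, percentile 85.1), 19 neuronal genes (-0.01, percentile 0.62, or 29.0 among lists not matched on level), 8 reference genes (0.28, percentile 71.7), 10 choroid plexus markers (-0.43, percentile 0.24) or 3 platelet markers (-0.02, percentile 47.4). The choroid plexus median turned to 0.18 (percentile 59.2) with the floor at 100. The kynurenine list no longer stood apart under 5 alternatives, with percentiles down to 90.95, nor did the cell death list with blank cells left out or set to 113 (down to 94.6). Bpgm, the measured red cell marker, had a log2 fold of 0.32. Of 13 myelin and oligodendrocyte genes the galactolipid synthase Ugt8a (4.45-fold) and the cytoskeletal protein Ermn (3.24-fold) fell, with a list median of -0.06 (percentile 7.88). The genes that fell most above the floor on both arrays were Arc, Mir124a-1hg (5.78-fold), the chaperone Chordc1 (5.49-fold, from 518 to 94.3), Ugt8a, the peroxisomal transporter Abcd2 (4.23-fold), the histone demethylase Kdm7a (3.97-fold), the oligodendrocyte precursor receptor Gpr17 (3.71-fold) and Fat2 (3.58-fold). The pituitary genes Pomc, Gh and Prl were again listed in the naive pool (83.0, 73.5 and 50.5) and blank in the ECM pool, with a median of -0.56 (percentile 5.15), which turned to 0.62 with blank cells set to 113.

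In 47 of the 247 genes called higher the naive cell was blank, and 148 were above the floor on both arrays. Of 56 other bright probe sets 40 (71.4%) passed the same way, against 12 of 33 (36.4%) for the genes called lower. The split between directions moved with the scaling of the arrays. Genes called higher made up 72.6% of the calls, but 59.3% (204 higher, 140 lower) with the deposited values unscaled and 56.2% (190 higher, 148 lower) after scaling to a common trimmed mean, which moved the median log2 fold of all genes from 0.07 to -0.04 and -0.06. The calls of Cd74, C1qb, Esam and Plvap ended under both of these scalings and that of Cd68 under the second. In CBA/CaH that of Mt2 ended under both. With the median of all probe sets, the calls of Abcd2, Cxcl9, Cxcl11, Ermn, H2-Aa and Socs3 ended. With blank cells set to 113 those of Ccl12, Ch25h, Cxcl9, Cxcl11, Fcgr4, Gzma, Hmox1 and Icam1 ended, as they did with the floor at 100, where those of Abcd2, Cd68, Cd74, Fat2 and Osmr ended too.

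**Figure D2:**
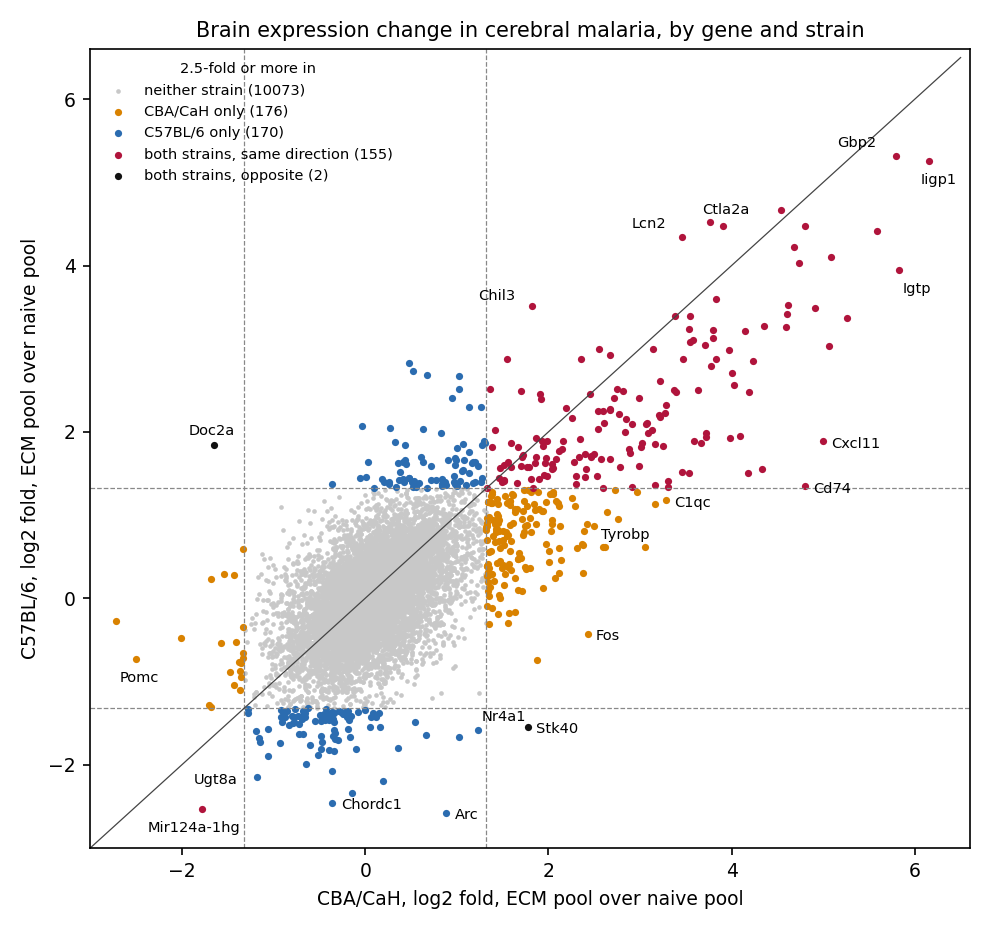
Log2 fold, ECM pool over naive pool, of each of 10576 genes measured in both strains, with CBA/CaH on the horizontal and C57BL/6 on the vertical axis, dashed lines at 2.5-fold and a solid line of equal folds. Points are coloured by the strains in which the gene passed, and most genes higher in both strains lay below the line of equal folds.

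Whether the strains shared their response was read from the genes measured in both. Of 309 such genes higher in CBA/CaH and 235 higher in C57BL/6, 154 were shared, where independent lists would share 6.87. Among the 309, 299 were also above their naive level in C57BL/6, and 231 of the 235 were above it in CBA/CaH. Genes blank or under the floor in a naive pool were measured there through their ECM value only. They could not lie below naive, so part of this agreement in sign was fixed beforehand. Genes called in 1 strain but not measured in the other, such as H2-Ab1, which had no value in either C57BL/6 pool, are left out. Mir124a-1hg was the 1 gene lower in both strains, against 0.21 for independent lists of 24 and 92 genes, but the count was 6 under each of 2 other scalings and 27 at a threshold of 2-fold. Across the 10576 genes, which are not independent replicates, the log2 folds correlated with Pearson's r = 0.65 and Spearman's rho = 0.56.

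Among genes called in at least 1 strain, folds differed between the strains by at least 2.5 times in 123. For 97 the ratio of ECM over naive was larger in CBA/CaH and for 26 it was larger in C57BL/6. Of the 97, 70 rose in CBA/CaH and 28 fell in C57BL/6. Above the floor on all 4 arrays the largest ratios in favour of CBA/CaH were those of Arc (11.0), Fos (7.23), Nr4a1 (6.99), Lyz1 (6.83), Ly86 (5.41) and C1qc (4.31). With the median of all probe sets the log2 ratio of Lyz1 went from 2.77 to 1.70, below those of Ly86 and C1qc, and the others were unchanged. Without probe sets of the _x_at and _s_at kinds Lyz1 had no ratio. Fos went from 214 to 1151 in CBA/CaH and from 543 to 404 in C57BL/6, and Arc from 153 to 283 and from 384 to 64.1. In favour of C57BL/6 the largest were Pcdhb21 (3.80), Pde1a (3.78), 2810410L24Rik (3.41), the carbonic anhydrase Car14 (3.31), Evi5 (3.27) and Mir9-3hg (2.83), of which Pcdhb21, Pde1a and Evi5 were under 2.5 with the median of all probe sets. By list, the median difference of the log2 folds, CBA/CaH minus C57BL/6, was 1.93 for 4 MHC class II genes, 1.5 for 14 microglia markers, 1.47 for 7 complement genes, 1.11 for 14 immediate early genes and 0.57 for 27 interferon-stimulated genes, each at the 100th percentile of matched random lists, and 0.03 (percentile 59.6) for 15 glucocorticoid-responsive genes. Larger folds in CBA/CaH were not particular to these lists. The difference was 0.90 for 12 chemokines, 0.68 for 16 reactive astrocyte genes and 0.65 for 14 genes of MHC class I and antigen processing (each at the 100th percentile). It was 0.80 (percentile 99.98) for 11 monocyte and macrophage markers and 0.77 (99.97) for 6 T cell and NK cell markers. On the other side lay 3 pituitary markers (-1.06, percentile 0.205), all blank in both ECM pools, and 2 neutrophil markers (-0.92). These list differences were computed after the data were seen, and C1qa, C1qb and C1qc belong to both the microglia and the complement list. With 1 pool per group none of the strain differences could be tested, and a blank cell was among the 4 values of 32 of the 97 genes and 10 of the 26.

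**Figure D3:**
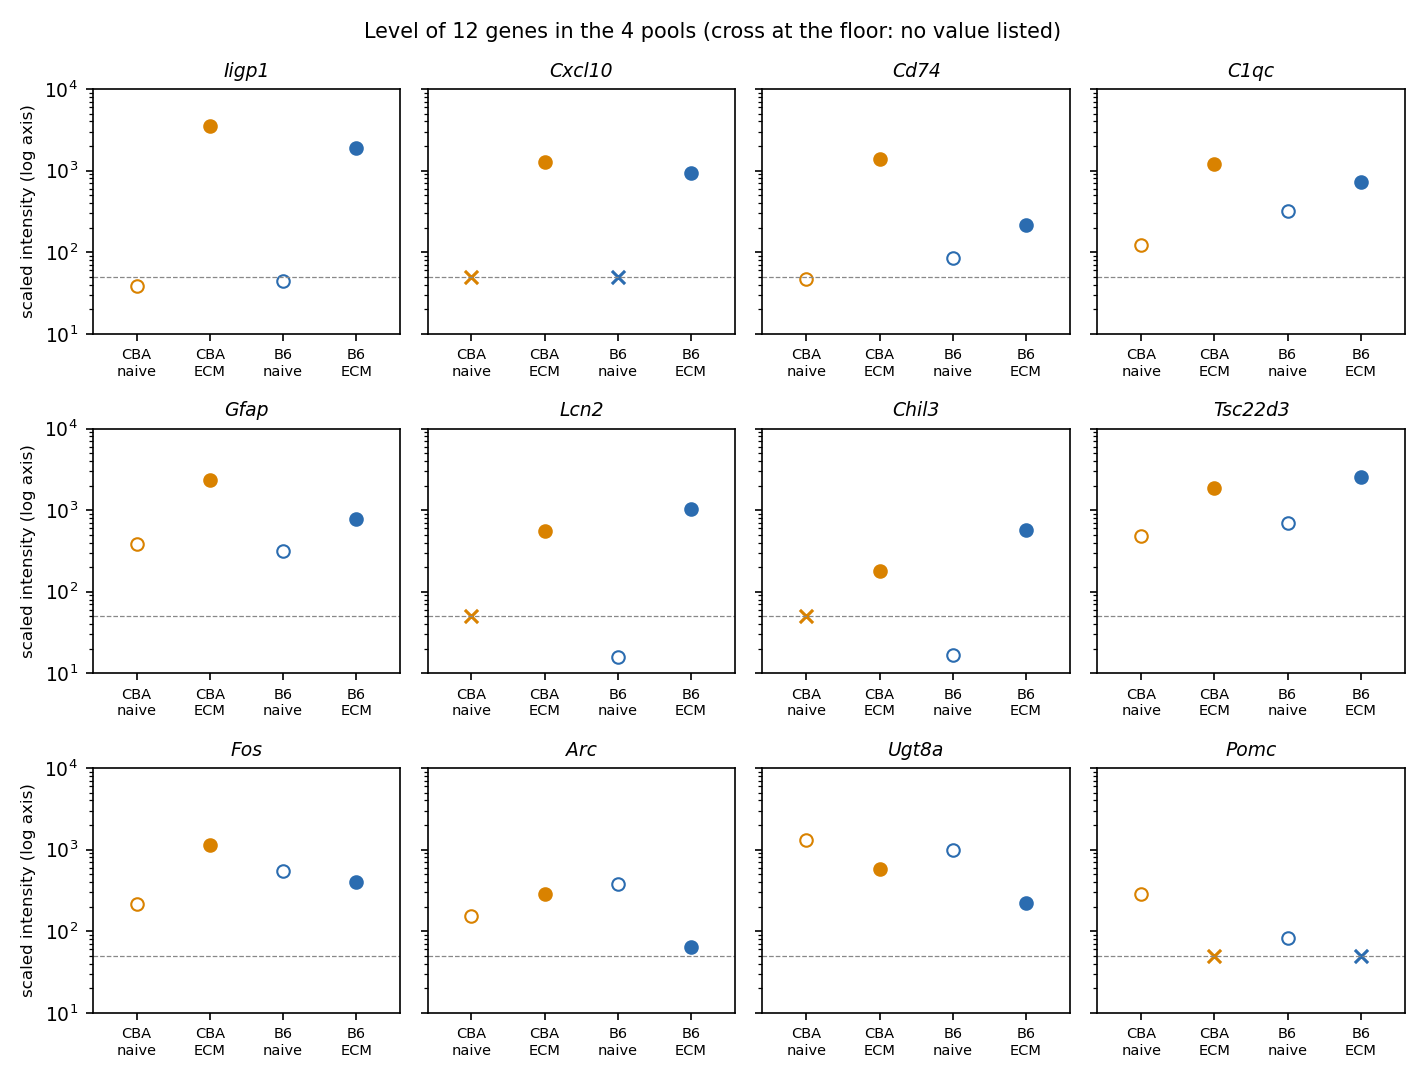
Scaled intensity, on a log axis, of 12 genes in the 4 pools of 6 mice each, for CBA/CaH (orange) and C57BL/6 (blue, B6), with open circles for naive and filled circles for ECM pools. The dashed line is the floor of 50 and a cross marks a cell with no value listed, as for Cxcl10 in both naive pools and Pomc in both ECM pools.

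Between the naive pools of the 2 strains 46 genes were higher in CBA/CaH and 79 in C57BL/6, of 10648 measured. The largest differences above the floor in favour of CBA/CaH were those of the actin regulator Cap1 (13.5-fold, 1551 against 115), the orphan receptor Gprc5b (6.56-fold), the RNA-binding protein Rbm45 (5.19-fold), Lsm11 (4.62-fold) and the sodium-calcium exchanger Slc8a1 (4.12-fold). Higher in C57BL/6 were Pttg1, also called securin (28.6-fold, 3189 against 112), the calcium-binding protein Efhd2 (13.1-fold), Qrich1 (6.72-fold), Smim10l1 (5.87-fold) and 1500011B03Rik (5.48-fold). Between the ECM pools the difference of Pttg1 was smaller, at 6.78-fold, with a CBA/CaH value of 581. The ECM pools differed in 117 genes higher in CBA/CaH and 102 higher in C57BL/6. In 55 genes the naive and the ECM pair differed the same way, 18 higher in CBA/CaH and 37 in C57BL/6, where independent lists would share 0.25 and 0.68. H2-Ea, which C57BL/6 mice do not express, had no value on any array and so did not check the strain labels.

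Other bright probe sets passed the same way in 12 of 24 cases (50.0%) for genes higher in the naive CBA/CaH pool and in 9 of 30 (30%) for genes higher in that of C57BL/6. In the opposite direction 2 of the 24 and 0 of the 30 passed. The calls of Gprc5b, Slc8a1, Smim10l1 and 1500011B03Rik ended when the median of all probe sets was taken, that of Efhd2 without probe sets of the _x_at and _s_at kinds, and that of Lsm11 with the floor at 100.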

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

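All tests of explanations in this part were chosen after the results were seen. No difference between the strains was tested against replicates, since each group was 1 pool.

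Immediate early genes had a median log2 fold of 0.94 in CBA/CaH and -0.22 in C57BL/6, on opposite sides of matched random lists, although 14 of 16 and 12 of 14 members did not pass the threshold. The position in C57BL/6 (percentile 1.76) was lost with the floor at 25, with the median of all probe sets and among lists not matched on level (up to 3.66). Both medians kept their sign under 5 scalings, from 0.88 to 0.94 and from -0.43 to -0.22. A higher naive level in C57BL/6 (naive-pair median, CBA/CaH over C57BL/6, of -0.47 over 13 genes) is argued against as the whole cause, since in the ECM pair the median was 0.76 over 16 genes (100th percentile). A difference between the strains, or in stage of disease or handling before death, stays open and untested.

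Doc2a, a calcium sensor of synaptic vesicles, fell in CBA/CaH (log2 fold -1.66) and rose in C57BL/6 (1.84), and the kinase-like Stk40 rose in CBA/CaH (1.78) and fell in C57BL/6 (-1.55). They were the only genes called in opposite directions, the difference was not tested, and in each comparison the lower side was a blank cell. All 4 calls ended with the floor at 100 and with blank cells set to 113.

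Microglia markers had smaller folds in C57BL/6, with a median of 1.49 in CBA/CaH and -0.16 in C57BL/6. A compression of all folds on the C57BL/6 arrays by 1 common factor is argued against. After allowing for the slope of the interferon-stimulated genes (0.82), the 14 markers still lay lower in C57BL/6 by a median of -1.12, below all matched random lists. Glucocorticoid-responsive genes had like medians in CBA/CaH and C57BL/6 (1.20 and 1.32). The random lists were not limited to induced genes, and some other induced lists also had smaller medians in C57BL/6 than that slope gives. These were MHC class II (3.24 and 1.0) and chemokines (1.67 and 0.84), among others. A compression of part of the induced genes is therefore not set aside. The naive C57BL/6 pool had the higher level, with a naive-pair median of -0.56 over 15 genes, yet in the ECM pair CBA/CaH was above C57BL/6 by a median of 0.85 over 13 genes (100th percentile), so the naive level alone is not enough. Here too the 2 pairs were not read over the same genes. A strain difference in microglia or in recruited macrophages, which share some of these markers, and a difference in disease stage at collection stay open and were not tested.

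Differences between the naive pools of the 2 strains were weighed because single arrays and sequence differences both bear on them. Random error of single arrays is argued against as the whole cause, since 55 genes differed the same way in the ECM pair, where independent lists would share 0.93 with an upper Poisson bound of 3. Signal that belongs to 1 probe set, as a sequence difference under a probe gives, stays open: 38.9% of 54 other bright probe sets passed the same way (exact 95% interval 25.9 to 53.1), below the 73.1% (63.8 to 81.2) of genes higher in ECM in CBA/CaH, and between the ECM pools the share was 51.7% of 29 (32.5 to 70.6) for genes higher in CBA/CaH and 15.4% of 26 (4.36 to 34.9) for genes higher in C57BL/6. In the opposite direction went 4 of the 29, all 4 past the threshold, and 9 of the 26, of which 1 passed it. For genes lower in ECM, where strain sequence plays no part, the share was 46.7% (21.3 to 73.4) in CBA/CaH and 36.4% (20.4 to 54.9) in C57BL/6, so a low share does not mark strain sequence. All these shares include bright probe sets with the other value blank or under 50, which had to pass 1 way. Their number was not counted, so the gap to 73.1% decides nothing. Differences in transcript level between the strains stay open for genes whose probe sets gave like values, such as Cap1 (log2 3.75 and 3.79).

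Probe sets without a gene symbol here were outside every comparison. Of 9160, 1776 were measured in CBA/CaH, where 23 rose and 42 fell, and 1629 in C57BL/6, where 36 rose and 22 fell, and 12 rose in both, where independent lists would share 0.57.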

How the results depend on the processing

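The 3 alternatives added after the data were seen concern blank cells and the scaling median. The correlation of log2 folds between strains stayed between 0.62 and 0.66 over the 12 settings in which it was recomputed. With the floor at 25, genes higher and lower in ECM numbered 518 and 89 in CBA/CaH and 395 and 213 in C57BL/6, with 234 higher and 16 lower in both, 219 and 74 with a larger fold in CBA/CaH and C57BL/6, 100 and 164 naive genes higher in CBA/CaH and C57BL/6, and 96 shared strain differences. With the floor at 100 these counts were 210 and 12, 150 and 37, 92 higher in both, 48 and 11, 23 and 42, and 35. At a threshold of 2-fold they were 543 and 120, 499 and 285, 254 and 27, 241 and 87, 104 and 157, and 99. These follow from the settings, which admit more or fewer genes. Genes lower in C57BL/6 numbered 140 with values unscaled and 148 after scaling to a trimmed mean. Genes lower in both strains, 1 in the reported setting, numbered 6 under each of these, 2 with quantile normalization, 3 with no floor, 4 with the median of all probe sets and 2 without _x_at and _s_at probe sets. With the median of all probe sets 47 genes were lower in CBA/CaH and 50 naive genes higher in C57BL/6. With values on both arrays only, 19 genes were lower in CBA/CaH and 16 had a larger fold in C57BL/6, as fewer genes were tested. Apart from those named, the cause was not tested. Of the genes called higher, 227 of 328 in CBA/CaH and 200 of 247 in C57BL/6 remained with values on both arrays only. Fewer of the others remained with the median of all probe sets: 11 of 31 lower in CBA/CaH, 47 of 93 lower in C57BL/6, and 20 of 46 and 30 of 79 naive genes higher in CBA/CaH and C57BL/6.

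Of list medians outside the random lists, 13 of 16 above them in CBA/CaH and 8 of 15 in C57BL/6 remained so under every alternative that gave a percentile, and below them 1 of 2 and 0 of 3. MHC class II in CBA/CaH and neutrophil markers in C57BL/6 are counted as remaining, though only 10 of 12 alternatives gave them a percentile. Reversed were choroid plexus markers in C57BL/6 (0.18 with the floor at 100), chemokines in C57BL/6 (-0.34 with no floor and with values on both arrays only, where most induced chemokines drop out for their blank naive cell), pituitary markers in CBA/CaH (0.10 with blanks at the 95th percentile), neuronal genes in C57BL/6 (0.0127 with the median over probe sets listed on all arrays) and the strain difference of cell death genes (-0.38 with the floor at 100); the cause was not tested. Of 1684 recomputed folds of named genes 1599 kept their side of the threshold, 85 lost it and none changed sign, 27 of the losses with the floor at 100, 24 with the median of all probe sets, 17 with blank cells set to 113 and the rest under the scalings and without _x_at and _s_at probe sets. No paired analysis was possible because each group was 1 pool, and no array could be left out. Blank cells, over 40% of each array and for a reason not given in the sources used here, limit what can be said of dim genes.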

Other observations

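The lists in this part, and the test in it, were chosen after the data were seen, so their percentiles are not independent evidence of direction.

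Genes of lipid droplets, lipolysis and fasting rose in both strains, in 7 of 11 measured cases in each, with a median log2 fold of 1.86 in CBA/CaH and 1.46 in C57BL/6 (both at the 100th percentile). Plin2, which coats lipid droplets, rose 5.30-fold and 2.74-fold, the triglyceride lipase Pnpla2 3.90-fold and 3.10-fold, Txnip, a sensor of glucose and redox state, 3.77-fold and 5.26-fold, and Angptl4, an inhibitor of lipoprotein lipase, 3.62-fold and 3.07-fold over the floor from blank cells. With the median of all probe sets the calls of Pnpla2 and Angptl4 ended in both strains, and those of Angptl4 also with blank cells set to 113. Pdk4 and Plin4 are also among the glucocorticoid-responsive genes. Genes that endothelium uses under shear and stress rose in 8 of 11 cases in each strain (medians 1.87 and 1.47, 100th percentile), among them Apold1 (at least 7.06-fold and 5.62-fold), Cd93 (3.83-fold and 3.55-fold), Icam2 (at least 4.12-fold and 2.93-fold), Adamts1 (2.95-fold and 3.10-fold) and the transcription factor Klf2 (3.72-fold and 2.71-fold), while the listed brain endothelial junction and transport genes stayed within the threshold except Esam, which is in both lists and is 1 of the 8, and Slco1c1. Whole brain was profiled, so the cells in which these genes rose are not known. With the floor at 100 the calls of Icam2 and Klf2 ended in both strains, as did those of Angptl4 and Plin4, and that of Cd93 in C57BL/6. Those of Plin2 and Klf2 in C57BL/6 ended after scaling to a trimmed mean, and that of Plin4 there under 3 scalings.

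Genes of differentiating oligodendrocytes and of sphingolipid synthesis fell in 8 of 11 measured cases in C57BL/6 (median -1.36, percentile 0.00) and in none of 12 in CBA/CaH (median -0.34, percentile 0.16). Beside Gpr17 and Ugt8a and Ermn, which are also in the myelin list, the fatty acid hydroxylase Fa2h fell 2.52-fold, the receptor Plxnb3 3.16-fold and the deiminase Padi2 3.26-fold in C57BL/6 (the call of Plxnb3 ended with the median of its 2 probe sets, at -1.18, and without _x_at and _s_at probe sets, those of Plxnb3 and Padi2 with the floor at 100, and that of Fa2h with the median over probe sets listed on all arrays), whereas the abundant structural transcripts Mbp (log2 fold 0.21), Mobp (0.04) and Cnp (0.29) were near their naive level. Of 10 nuclear noncoding and host-gene RNAs, 4 fell in CBA/CaH (median -1.13) and 2 fell and 1 rose in C57BL/6 (median -0.86), with Meg3 at 2.60-fold and 1.70-fold below naive. The 11 Meg3 probe sets ran from -2.24 to -0.20 in CBA/CaH and from -1.87 to 0.59 in C57BL/6, and its call ended without _x_at and _s_at probe sets.

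Cirbp, a cold-inducible RNA-binding protein, rose 2.57-fold in CBA/CaH and 5.70-fold in C57BL/6 (from 294 to 1674), but the call in CBA/CaH ended under 3 scalings. Mice with ECM are known to become hypothermic, and a lower brain temperature is a hypothesis for this rise. It also predicts low heat shock chaperones, and the test left it open. The median log2 fold of 16 chaperones was 0.01 in each strain, and the higher of the 2 percentiles among matched random lists was 17.8. Chordc1 and Hsph1 (log2 folds of -2.46 and -1.03 in C57BL/6) were the members furthest below naive there, and Hspa1a and Hspa1b were above it (0.70 and 0.24). A median near 0 over members that went both ways decides nothing.

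Control transcripts added to the samples were not level over the arrays. After scaling, 18 probe sets of the hybridisation controls were brightest in the naive CBA/CaH pool, 1.86 times the naive C57BL/6 pool, and 24 probe sets of the poly-A controls were brightest in the C57BL/6 ECM pool, 2.09 times the naive C57BL/6 pool. The 3' over 5' ratio of Actb lay between 1.38 and 1.52 and that of Gapdh between 0.721 and 0.775 over the 4 arrays.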
